A study of Drosophila melanogaster with 9 samples.

How the data were processed

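The deposited files hold 1 column of TPM per library, which the authors made before deposit; the submitters' processing notes name Salmon and DESeq2 without versions or roles, and the genome build is not given in the sources used here. The TPM of a library sum to slightly under the fixed total (999685 to 999850), so a small part of it lies outside the genes listed. The authors also deposited 2 tables of log2 fold changes with their standard errors, which per the file headers compare Chd1-deficient with wild-type and with elav>Chd1 libraries and by their title lines hold only genes with an absolute log2 fold change of at least 1 (the smallest listed values are 0.9999 and 1.001). Each table also holds a p-value and an adjusted p-value per gene, deposited by the authors under the column names that DESeq2 uses. A test score, the fold change over its error, stands beside them as deposited by the authors. From these tables, which hold part of the genes, the text takes the number of genes listed, their signs and the fold change of Chd1.

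Libraries were matched to genotypes by the sample labels. All 16837 gene symbols were looked up in the Ensembl 115 annotation of BDGP6.54 (dm6) and a synonym table; 16016 matched a current symbol, 752 matched through 1 synonym, and 16768 had coordinates. The planned test for counts could not be used, because the files hold TPM, so the test set beforehand for normalized values was run. Values were transformed to log2(TPM + 0.5), and limma-trend fitted all 9 libraries together with 1 mean per genotype and contrasts between genotypes. Adjusted p is Benjamini-Hochberg over the 11094 genes with at least 1 TPM in at least 3 libraries, and the threshold was 0.05. That filter was chosen after the unit was known, because the planned one applies to counts. No further scaling was applied; the median log2 fold changes of all genes were -0.05 (Chd1-deficient against wild type), -0.02 (Chd1-deficient against elav>Chd1) and -0.15 (elav>Chd1 against wild type). On the median-ratio scale, another way to align libraries, they would be -0.03, -0.05 and -0.10.

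The 35 gene lists, the comparisons, the alternatives and the rule for naming genes were written before the data were examined. Lists with at least 5 tested members (33) were tested with limma's camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg over lists within a comparison. Camera with an estimated correlation stood beside it. Gustatory receptors (4 tested members) and genes of the mitochondrial genome (0 in the files) were not tested. Genes named in the text are Chd1, the 8 largest rises and falls (5 for elav>Chd1 against wild type) among called genes with a group mean of at least 5 TPM and libraries that do not overlap between groups, and in each list the 2 with the largest absolute fold change among its called members with the smallest p (4 members in lists called by camera, otherwise 2). To these come the called genes around Chd1 and, for the overlap, the 5 genes per direction with the largest smaller fold change. Genes outside this rule are marked as chosen after their values were seen.

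The overlap of the comparisons that share the Chd1-deficient libraries was set against 100 simulated datasets without differences. Genes around Chd1 are those whose annotated start lies within 100000 bases of it. List differences in the closing section were tested with 100000 permutations of genes between the lists.

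The procedure was tried on simulated TPM tables with known changes before use. Of genes changed by 0.5 on the log2 scale 73.91% to 75.51% were recovered, of those changed by 1, 92.00% to 100.00%, of those changed by 2, 98.00% to 100.00%, and of those changed by -1, 91.11% to 97.78%. Unchanged genes were called in 0.09% to 0.42% of cases. These rates cover genes that passed the filter, 41 to 50 of each changed size among 10148 to 10165. In the real data most genes were called, so the rates need not carry over.

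Alternatives changed 1 choice at a time: no filter, at least 10 TPM in 3 libraries, only the 2 groups compared in the fit, each library left out, replicate number as a block, median-ratio scaling, pseudocounts of 0.1 and 1, an absolute log2 fold change of at least 1, and the estimated correlation. A robust prior was added after seeing the data. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.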

Results

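Per the labels, the series measured RNA from heads of virgin Drosophila melanogaster females, 10 days old, in 3 genotypes with 3 libraries each. The tissue and sex given by the labels are in doubt. Eggshell transcripts were abundant in every library, and male transcripts were present in every group and highest in the Chd1-deficient one (values below). No value can therefore be assigned to head tissue alone. Chd1 encodes a chromodomain helicase that remodels nucleosomes. The genotypes were wild type, a Chd1 deletion (here Chd1-deficient), and flies in which the pan-neuronal driver elav-Gal4 expresses a Chd1 transgene (here elav>Chd1). The sample labels call the elav>Chd1 group rescued, while the series text lists rescued flies apart from it and names no wild type. Whether elav>Chd1 flies carry the deletion is not stated outright. The group labelled wild type, the reference of 2 comparisons, may therefore carry a restored copy of Chd1. The deposited values are TPM, transcript abundances scaled to a fixed library total, for 16837 genes, so each library sums to about the same total (999685 to 999850) and its sequencing depth is unknown. Between 13558 and 14835 genes lay above 0 in a library. At least 1 TPM was reached by 9159 to 9253 genes in the wild-type libraries, by 9743 to 9787 in the elav>Chd1 libraries and by 11142 to 11220 in the Chd1-deficient libraries. Levels below are the mean ± SD in TPM (n = 3 libraries per group), and fold changes are on the log2(TPM + 0.5) scale, which understates the change of low genes. Labels do not say that the 3 libraries of a genotype came from separate pools of flies, so the p-values measure the spread between these libraries, which may be technical.

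Chd1, the deleted gene (FBgn0250786; chromosome 2L, 2979562 to 2987723 in the dm6 assembly), was measured first as a check of the labels. Its level was 101.6 ± 8.12 TPM in the wild-type libraries, 19.45 ± 1.08 TPM in the Chd1-deficient libraries and 63.5 ± 0.314 TPM in the elav>Chd1 libraries. All 3 groups were separated from one another. Chd1 fell by 2.35 on the log2 scale (SE 0.06, limma adjusted p = 2.4e-10) from wild type to Chd1-deficient, and by 0.67 (SE 0.06, limma adjusted p = 5.9e-06) from wild type to elav>Chd1. Against elav>Chd1, the Chd1-deficient libraries were lower by a log2 fold change of -1.68 (SE 0.06, limma adjusted p = 4.5e-09). The authors' deposited table gives -2.304 and -1.691 for the 2 comparisons with the Chd1-deficient group. Chd1 transcript therefore remained measurable in the Chd1-deficient libraries.

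**Figure D1:**
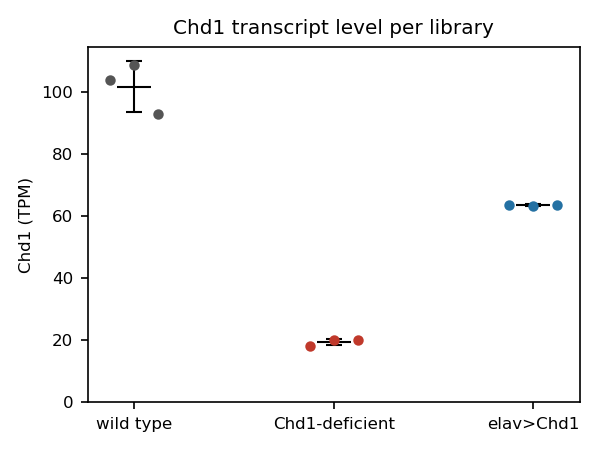
Chd1 level in TPM (y axis) in each library of the 3 genotypes (x axis); points are libraries and the black marks give the mean with its SD. The Chd1-deficient libraries lie at 19.45 ± 1.08 TPM, the elav>Chd1 libraries at 63.5 ± 0.314 TPM and the wild-type libraries at 101.6 ± 8.12 TPM.

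The comparison of Chd1-deficient with wild-type libraries asks which transcripts differ in flies labelled with the Chd1 deletion. Genes of muscle, neurons, the eye, cuticle, immune peptides and the male reproductive tract were higher in the Chd1-deficient libraries, and genes of chromatin remodelling complexes and the proteasome were lower. Act88F, the actin of the indirect flight muscles, rose from 31.97 ± 0.385 to 319.7 ± 9.54 TPM, and nSyb, the synaptobrevin of neurons, from 15.5 ± 0.178 to 82.5 ± 1.46 TPM. Mtk, an antimicrobial peptide gene, rose from 47.2 ± 5.47 to 699.4 ± 42.1 TPM. Of 11094 genes tested, 9859 were called, 4758 higher and 5101 lower, at a limma adjusted p under 0.05. With an absolute log2 fold change of at least 1, 3231 were called, of which 3003 were higher and 228 lower. A gene can pass the filter through the Chd1-deficient libraries alone, which can favour large rises. At least 1 TPM was reached there by 11142 to 11220 genes, against 9159 to 9253 in wild type. The median log2 fold change of all genes was -0.05. Y chromosome and roX RNA differed between these groups too (below), so any of these calls may carry a difference in sex or tissue.

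Genes of several tissues rose together. All 26 tested muscle genes were higher (median log2 fold change 2.25), as were all 12 neuron markers (median 2.09). Limma's camera test, with a preset correlation of 0.01 between genes, called both (adjusted p = 1.2e-11 and 1.2e-05), and both calls were lost at adjusted p = 0.123 and adjusted p = 0.274 with an estimated correlation. Among the photoreceptor genes, 27 of 29 were higher and 2 lower, with a median of 2.03 (camera adjusted p = 3.3e-09, adjusted p = 0.135 with an estimated correlation). Rh3, an opsin, rose from 37.4 ± 1.74 to 189.9 ± 3.33 TPM (log2 fold change 2.33, limma adjusted p = 1.1e-11). The level of trp, a channel of the photoreceptor light response, rose from 19.96 ± 0.687 to 101.9 ± 2.87 TPM. Of 46 genes of synaptic transmission 44 were higher (camera adjusted p = 1.1e-10, adjusted p = 0.260 with an estimated correlation), among them para, the voltage-gated sodium channel, at 16.55 ± 0.784 against 3.01 ± 0.187 TPM. Neuropeptide genes were higher in 37 of 41 cases, and Nplp3 went from 175.8 ± 13.8 to 2490 ± 76.3 TPM. Of 49 cuticle protein genes 40 were higher and 4 lower, with a median of 2.02, and Cpr92F rose from 3.31 ± 0.126 to 104.4 ± 2.24 TPM. Odorant-binding and antennal proteins were higher in 27 of 34 cases. Obp56e rose from 4.8 ± 0.527 to 144.4 ± 7.51 TPM. The files hold 123 cuticle and 117 odorant-binding and antennal genes, so most of both lists failed the filter. Members that passed it only through the Chd1-deficient libraries would favour a rise. Glia markers were higher in 10 of 14 cases and lower in 2 (camera adjusted p = 0.013, adjusted p = 0.322 with an estimated correlation), including Gs2, a glutamine synthetase, at 215 ± 10.3 against 53.3 ± 0.425 TPM. The lists of 5 further groups were called higher with smaller medians, namely fat body (20 of 28 higher, median 0.50), digestive enzymes (34 of 44, median 0.65), cytochrome P450 enzymes (51 of 66, median 0.69), glutathione and UDP-glycosyl transferases (41 of 52, median 0.72) and oxidative phosphorylation (75 of 78, median 0.53). All 5 limma calls were lost with an estimated correlation, at adjusted p = 0.260, 0.274, 0.216, 0.135 and 0.086 in this order.

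In all, camera called 20 of 33 lists with the preset correlation, 16 higher and 4 lower, and 4 with an estimated correlation. The limma call was then kept for cuticle proteins (adjusted p = 0.017), neuropeptides (0.019), odorant-binding and antennal proteins (0.019) and the male list (0.019). Tested were 49 of 123, 41 of 46, 34 of 117 and 23 of 30 members in this order, and the filter can favour a rise. Counts of members adjusted over the list alone equalled those over all genes in 89 of the 99 list and comparison pairs and differed by at most 3 members in the other 10.

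The same libraries held abundant transcripts of the ovary. Vm26Aa, which encodes an eggshell protein, stood at 6243 ± 569 TPM in the wild-type, 8708 ± 324.5 TPM in the Chd1-deficient and 7371 ± 318.8 TPM in the elav>Chd1 libraries. The maternal gene osk stood at 632.9 ± 52.1, 423.9 ± 14.8 and 563.1 ± 17.04 TPM in the same order. In each library these genes lay far above elav, the neuronal marker whose promoter drives the transgene, at 1.11 ± 0.217, 3.56 ± 0.210 and 1.92 ± 0.024 TPM. Of 25 ovary and eggshell genes, 16 were lower and 6 higher in the Chd1-deficient than in the wild-type libraries, and the list was not called (median -0.46, limma camera adjusted p = 0.057). The chorion genes Cp36 and Cp7Fc fell by 1.03 and 1.22 on the log2 scale. Vm26Aa, osk and elav were chosen for mention after their values were seen.

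Antimicrobial and immune-induced peptides formed one of the strongest groups. Of 36 tested, 33 were higher and 1 lower, with a median log2 fold change of 1.87 (33 and 1 when adjusted over the list alone). AttA, an attacin, rose from 10.98 ± 0.778 to 134 ± 3.18 TPM. Among the 8 largest rises were edin, at 84.1 ± 8.05 against 2.19 ± 0.398 TPM, and IM18, at 922.6 ± 94.3 against 32.9 ± 12.3 TPM. The camera adjusted p was 1.9e-09, and with an estimated correlation it was 0.052, just over the threshold. The pathway receptors and signalling proteins of the same immune response were not called as a list (19 of 37 higher, 16 lower, camera adjusted p = 0.478), although PGRP-SB1, a peptidoglycan recognition protein, rose by 2.23 on the log2 scale (SE 0.08, limma adjusted p = 2e-09). TotM, a stress-induced Turandot peptide, went from 18.8 ± 1.46 to 100.9 ± 0.948 TPM, while the list it belongs to had 5 members higher and 4 lower.

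Genes of the male germline and accessory gland were higher in 21 of 23 cases and lower in none (median 2.28, limma camera adjusted p = 2.8e-06). Mst84Da and Mst87F, genes of the male germline, stood at 66.5 ± 4.45 and 75.5 ± 8.76 TPM in the Chd1-deficient libraries, against 4.67 ± 0.431 and 6.65 ± 1.27 TPM in wild type. The dosage compensation RNA roX1, named after its values were seen, stood at 27.5 ± 1.8 TPM in the Chd1-deficient libraries against 1.98 ± 0.313 in wild type and 1.95 ± 0.079 in elav>Chd1. Genes of the Y chromosome, 50 in the files, summed to 7.33 to 9.95 TPM in the Chd1-deficient libraries and to at most 0.621 TPM in any other library. All 9 samples are labelled female.

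**Figure D2:**
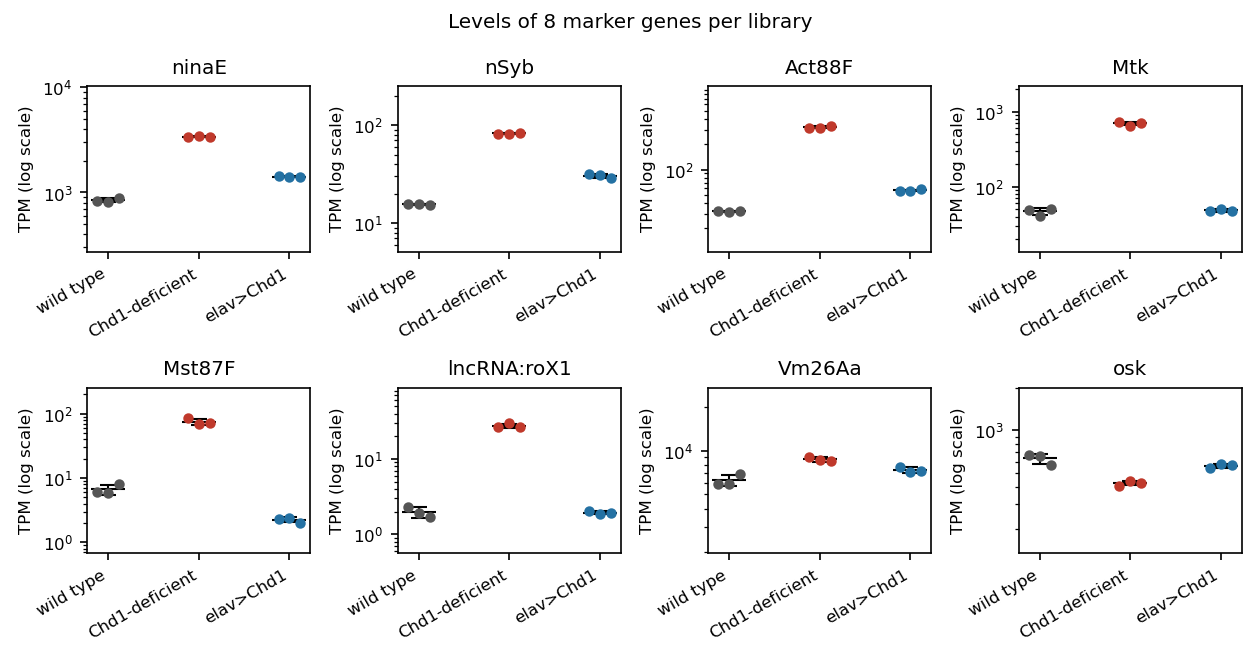
Levels in TPM on a log axis for 8 genes in each library, with the mean and its SD in black. ninaE, nSyb, Act88F, Mtk, Mst87F and lncRNA:roX1 were highest in the 3 Chd1-deficient libraries, where Mst87F lay at 75.5 ± 8.76 TPM, whereas osk was lowest there at 423.9 ± 14.8 TPM.

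Among groups that fell, chromatin remodellers and histone chaperones were lower in 34 of 35 cases and higher in none (median -0.65, camera adjusted p = 2.6e-08, adjusted p = 0.304 with an estimated correlation). Mi-2, a nucleosome-remodelling ATPase, fell from 78.2 ± 6.05 to 37.2 ± 1.72 TPM, and Caf1-55, a histone chaperone, from 228.5 ± 10.3 to 142.2 ± 1.26 TPM. Germline genes, chosen after their values were seen, fell by similar amounts, nos from 339.5 ± 45.1 to 185.6 ± 9.44 TPM and aub from 61.8 ± 5.04 to 39.1 ± 1.19 TPM. Proteasome subunits were lower in 31 of 32 cases (median -0.36, camera adjusted p = 4.2e-07, adjusted p = 0.180 with an estimated correlation). Mitochondrial ribosomal proteins (38 of 74 lower, 9 higher; adjusted p = 0.018, and adjusted p = 0.123 with an estimated correlation) and ribosome biogenesis factors (19 of 29 lower, 4 higher; adjusted p = 0.045, and adjusted p = 0.677 with an estimated correlation) were also called lower. Their medians were -0.11 and -0.22 in this order, against -0.05 for all genes. Cytosolic ribosomal proteins were called higher with a median of 0.10 (49 of 84 higher, 12 lower, camera adjusted p = 0.045, adjusted p = 0.708 with an estimated correlation). Hsp26, a small heat shock protein, fell from 2069 ± 41.7 to 815.5 ± 18.7 TPM, but the heat shock and chaperone list was not called and had 13 of 22 members higher and 7 lower (median 0.64, limma camera adjusted p = 0.201). Its member Hsp70Ab, one of several near-identical copies, was listed at 0 in the wild-type libraries and at 13.33 to 27.30 TPM in the Chd1-deficient ones.

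Among the largest falls were CG13159, from 33.5 ± 6.3 to 0.454 ± 0.220 TPM, CG31813, from 15.5 ± 2.44 to 0.303 ± 0.163 TPM, and CG9184, from 20.02 ± 1.68 to 0.774 ± 0.330 TPM. The linker histone copy His1:CG33837 was listed at 0 in all 3 Chd1-deficient libraries and at 254.5, 201.7 and 229.7 TPM in the wild-type libraries. Histone copies are near-identical, so its level is uncertain. CG46312 and SdicA were listed at 0 in all Chd1-deficient and all elav>Chd1 libraries, and in wild type at 20.55 to 58.49 TPM and at 5.378 to 8.761 TPM. CG11458 had the largest rise, from 1.04 ± 0.671 to 142.3 ± 13.9 TPM. Among the markers of transgenes and genetic background, w, an eye pigment transporter, fell from 13.9 ± 0.577 to 1.86 ± 0.149 TPM and se rose from 3.62 ± 0.786 to 29.96 ± 3.06 TPM. The authors' deposited table lists 5307 genes for this comparison, 5069 of them higher. Of these, 3574 were tested here and all 3574 had the same sign.

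The comparison of Chd1-deficient with elav>Chd1 libraries asks where flies labelled with the deletion differ from flies that express Chd1 from the neuronal driver. w stood at 1.86 ± 0.149 against 10.12 ± 0.846 TPM and se at 29.96 ± 3.06 against 4.7 ± 0.341 TPM, so these groups may also differ in genetic background. Male genes and immune peptides had the largest medians of all lists. DptA, a diptericin, stood at 411 ± 16.6 TPM in Chd1-deficient and 22.5 ± 1.77 TPM in elav>Chd1 libraries, and AttC at 224.1 ± 1.02 and 13.1 ± 0.510 TPM. Of 36 antimicrobial peptides 34 were higher and 1 lower in Chd1-deficient (median 2.30, camera adjusted p = 5.7e-14, adjusted p = 0.022 with an estimated correlation). Male genes were higher in 22 of 23 cases (median 3.88, camera adjusted p = 5.2e-11, adjusted p = 0.009 with an estimated correlation). In total 7583 of 11094 genes were called by limma, 3847 higher and 3736 lower, and 1921 of these had an absolute log2 fold change of at least 1 (1751 higher, 170 lower). With median-ratio scaling the balance turned, to 3764 higher and 4501 lower. Genes that pass the filter through the Chd1-deficient libraries alone can favour large rises here too. With genes of at least 10 TPM in 3 libraries only, 7472 genes were tested and 4994 were called.

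Nervous system and eye genes were higher in Chd1-deficient than in elav>Chd1 libraries as well, with smaller medians than against wild type. All 12 neuron markers (median 1.29) and 42 of 46 synaptic genes (median 1.08) were higher, among them ple, tyrosine hydroxylase, at 27.6 ± 0.997 against 6.68 ± 0.320 TPM. The phototransduction list had 26 of 29 genes higher (median 1.20) and the neuropeptide list 34 of 41 (median 0.85). Camera called these 4 lists, with adjusted p = 3.4e-06, 4.7e-12, 2.3e-10 and 1.9e-07, and with an estimated correlation adjusted p = 0.379, 0.345, 0.176 and 0.022. Muscle genes were higher in 22 of 26 cases with a median of 0.48 (camera adjusted p = 2.6e-06, adjusted p = 0.345 with an estimated correlation), and fln, a flight muscle protein, stood at 164.8 ± 4.6 against 50.5 ± 1.32 TPM. Cuticle protein genes were higher in 34 of 49 cases and lower in 6 (median 0.92, adjusted p = 4.6e-05, adjusted p = 0.022 with an estimated correlation), and oxidative phosphorylation genes were higher in 65 of 78 (median 0.22, adjusted p = 6.0e-08, adjusted p = 0.176 with an estimated correlation).

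Ovary and eggshell genes were lower in Chd1-deficient libraries in 16 of 25 cases and higher in 4 (median -0.24, camera adjusted p = 3.0e-04, adjusted p = 0.033 with an estimated correlation). The chorion gene Cp38 stood at 817 ± 15.03 TPM in Chd1-deficient and 2481 ± 76.3 TPM in elav>Chd1 libraries. Lipid metabolism genes were lower in 19 of 25 cases (median -0.26, camera adjusted p = 0.001, adjusted p = 0.581 with an estimated correlation). Of these, Lsd-1, a lipid droplet protein, fell by 1.32 on the log2 scale and FASN1, a fatty acid synthase whose gene lies near Chd1, by 1.31. Chromatin remodellers were lower in 28 of 35 cases and higher in 1 (median -0.25, camera adjusted p = 3.4e-06, adjusted p = 0.550 with an estimated correlation). Proteasome genes (17 of 32 lower, 3 higher, camera adjusted p = 0.020, adjusted p = 0.581 with an estimated correlation) were called lower (median -0.09). So were cytosolic ribosomal proteins (31 of 84 lower, 11 higher, camera adjusted p = 0.024, adjusted p = 0.689 with an estimated correlation), but their median of -0.04 lay near that of all genes (-0.02). CG13159 (0.454 ± 0.220 against 103.2 ± 8.77 TPM) and CG31813 (0.303 ± 0.163 against 36.6 ± 1.79 TPM) were again among the largest falls, and CG43816 was listed at 0 in the elav>Chd1 libraries and at 18.34 to 23.40 TPM in the Chd1-deficient ones. The authors' deposited table lists 3546 genes, 3276 of them higher, and the 2238 tested here all had the same sign.

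The comparison of elav>Chd1 with wild type asks where these groups differ. Muscle genes were higher in elav>Chd1 in all 26 cases (median 1.70, camera adjusted p = 4.9e-19, adjusted p = 0.054 with an estimated correlation), including Act79B at 393.7 ± 8.45 against 82.8 ± 4.24 TPM. Neuropeptide genes were higher in 33 of 41 cases (median 0.82, adjusted p = 1.0e-09, adjusted p = 0.014 with an estimated correlation) and cuticle genes in 29 of 49 (median 0.61, adjusted p = 5.9e-08, adjusted p = 0.010 with an estimated correlation). The antimicrobial peptide list was not called (6 higher, 19 lower, median -0.25, limma camera adjusted p = 0.218), and its members went both ways, with Drs at 1279 ± 46.1 against 589.9 ± 47.8 TPM and IM1 at 91.8 ± 2.77 against 168.1 ± 7.89 TPM. Male genes were lower in elav>Chd1 in 20 of 23 cases and higher in 1 (median -1.21, camera adjusted p = 6.0e-04, adjusted p = 0.048 with an estimated correlation), and Acp53Ea fell from 6.05 ± 0.284 to 1.12 ± 0.559 TPM. Genes of the Y chromosome summed to 0.133 to 0.208 TPM in elav>Chd1 and to 0.428 to 0.621 TPM in wild type.

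LysD, a lysozyme of the gut, stood at 2028 ± 85.7 TPM in elav>Chd1 against 271.4 ± 45.1 TPM in wild type, and digestive enzymes were higher in 33 of 44 cases (median 0.56, camera adjusted p = 8.8e-10, adjusted p = 0.137 with an estimated correlation). GstE1, a glutathione transferase, rose from 12.1 ± 0.886 to 71.5 ± 5.05 TPM, and its list was higher in 32 of 52 cases and lower in 8 (camera adjusted p = 1.5e-05, adjusted p = 0.102 with an estimated correlation). Chromatin remodellers were lower in 33 of 35 cases (median -0.43, camera adjusted p = 4.1e-07, adjusted p = 0.323 with an estimated correlation), and proteasome subunits in 30 of 32 (median -0.29, adjusted p = 3.3e-07, adjusted p = 0.165 with an estimated correlation). The germline genes nos and aub stood at 253 ± 8.03 and 45.9 ± 1.59 TPM in elav>Chd1 against 339.5 ± 45.1 and 61.8 ± 5.04 TPM in wild type. Ovary and eggshell genes were not called (11 higher, 11 lower, limma camera adjusted p = 0.148). In all, 8642 genes were called by limma, 3394 higher and 5248 lower, and 937 had an absolute log2 fold change of at least 1. Nervous system and eye genes were above wild type too, with 12 of 12 neuron markers (median 0.85), 41 of 46 synaptic genes (median 0.76) and 26 of 29 photoreceptor genes (median 0.74) higher. Camera called these 3 lists (limma adjusted p = 1.7e-06, 9.7e-11 and 3.2e-10), and the calls were lost at adjusted p = 0.235, 0.235 and 0.109 with an estimated correlation. Odorant-binding and antennal proteins (27 of 34 higher, 5 lower) and mitochondrial ribosomal proteins (52 of 74 lower, 1 higher) kept their limma call, at adjusted p = 0.010 and 0.029 with an estimated correlation. The median of the mitochondrial ribosomal proteins was -0.19, against -0.15 for all genes. Camera called 22 of the 33 lists, 17 of them higher, and 5 with an estimated correlation.

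**Figure D3:**
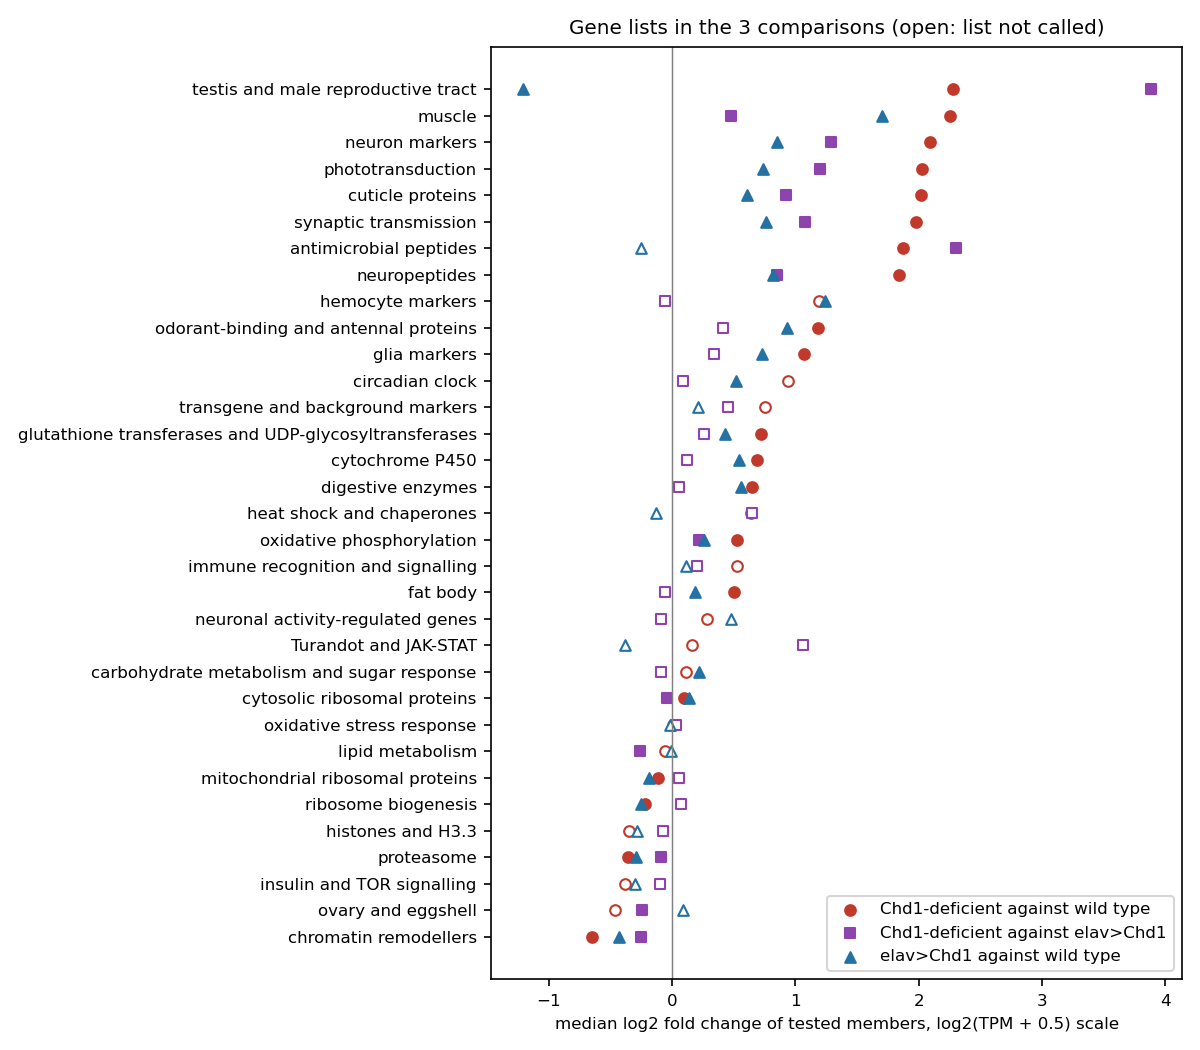
Median log2 fold change of the tested members of each of 33 gene lists (x axis, on the log2(TPM + 0.5) scale; y axis, lists) in the 3 comparisons; filled symbols mark lists called by camera with the preset correlation. Muscle genes have a median of 2.25 in Chd1-deficient and 1.70 in elav>Chd1 against wild type, whereas antimicrobial peptides have 1.87 and -0.25.

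The comparisons of the Chd1-deficient group with wild type and with elav>Chd1 overlapped. Genes higher in both numbered 3491 and genes lower in both 3196, while 434 went opposite ways. Among the genes higher in both by the widest margin were the immune peptide genes CecA1, at 188 ± 5.04 TPM against 8.06 ± 1.91 in wild type and 6.85 ± 2.02 in elav>Chd1, and edin. Independent lists of these sizes would share 1650 higher and 1718 lower genes. Both comparisons use the same 3 Chd1-deficient libraries. In 100 simulated datasets that keep the shared libraries but hold no difference, the number of genes called in both was 0, which leaves out how shared libraries act where real differences exist. The fold changes correlated across genes at r = 0.826, against 0.494 in the simulated data, and their covariance was 0.855 against 0.0121, a difference of 0.843. Genes are not independent replicates, 3 shared libraries are too few to split, and part of the excess may come from them, including any difference in sex or tissue that they carry. At 10 TPM in 3 libraries the number called in both, 6687, dropped to 4356.

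**Figure D4:**
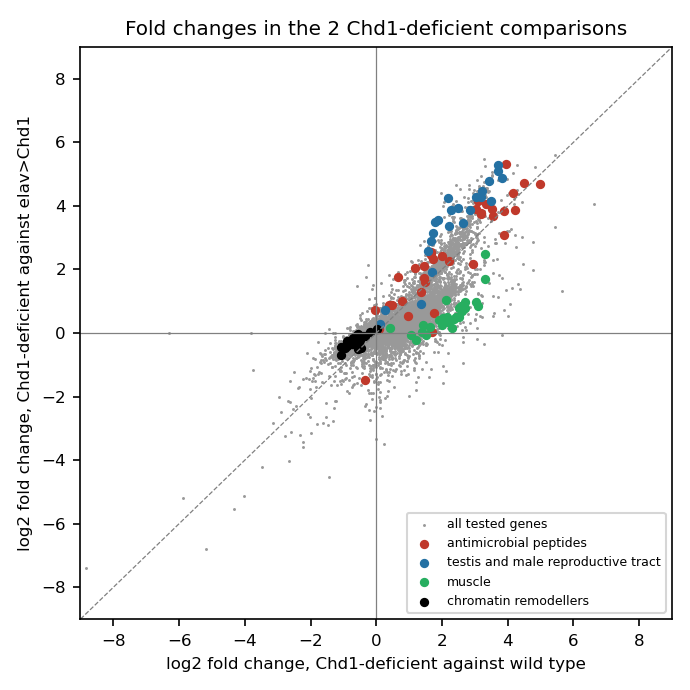
Log2 fold change of each of 11094 tested genes in Chd1-deficient against wild type (x axis) and against elav>Chd1 (y axis), with the dashed line marking equal values. Antimicrobial peptides lie near that line (medians 1.87 and 2.30), and muscle genes lie below it (medians 2.25 and 0.48).

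Of 4758 genes higher in Chd1-deficient than in wild type, 1096 (23.03%) were lower in elav>Chd1 than in Chd1-deficient and not called against wild type by limma, 3037 (63.83%) were also higher in elav>Chd1 than in wild type (1873 of them at a level between the other groups, 860 not called against Chd1-deficient), and 522 were lower there than in wild type. Of 5101 lower genes, 403 (7.90%) were higher in elav>Chd1 than in Chd1-deficient and not called against wild type, 4446 (87.16%) were also lower in elav>Chd1 than in wild type (2694 of them between the other groups, 1622 not called against Chd1-deficient), and 99 were above wild type. The peptide genes DptA and AttC passed below wild type, at 22.5 ± 1.77 against 47.7 ± 3.04 TPM and 13.1 ± 0.510 against 21.9 ± 1.79 TPM, whereas muscle and chromatin remodeller genes kept medians of 1.70 and -0.43. A gene that misses the threshold against wild type is not shown to equal it. The total of 1499 genes (1096 and 403) changed to 788, 846 and 851 when Chd1-deficient replicate 1, 2 or 3 was left out, to 570 at 10 TPM in 3 libraries, to 938 with only the groups compared in each fit and to 2953 without a filter.

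Genes within 100000 bases of Chd1 were described apart, because a deletion can affect its surroundings. Of 28 tested neighbours, 19 were lower and 6 higher in Chd1-deficient than in wild type, a share called of 89.29% against 88.87% of all genes. Against elav>Chd1, 22 were lower and 3 higher (89.29% called against 68.35% of all genes), with a median of -0.53. Between elav>Chd1 and wild type, 13 were higher and 6 lower in elav>Chd1 (67.86% called against 77.90% of all genes), with a median of 0.17. CG9641 had the largest fall against wild type, from 159.3 ± 6.69 to 82 ± 2.23 TPM, and lies at 2974859 to 2976862 on chromosome 2L. In elav>Chd1, FASN1 (110.2 ± 1.28 against 40.9 ± 1.88 TPM) and FASN2 (10.3 ± 0.293 against 2.04 ± 0.180 TPM), both fatty acid synthase genes, were higher than in wild type. Rbp9, an RNA-binding protein of neurons, rose by 1.52 on the log2 scale (SE 0.06, limma adjusted p = 3.4e-09) in Chd1-deficient against wild type.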

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

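Across all alternatives no called direction turned, and the number of genes called per comparison stayed within 1.5 times except where given here. Leaving out each library in turn gave 8559 to 9982 genes for Chd1-deficient against wild type, 5715 to 8292 against elav>Chd1 and 8108 to 8770 for elav>Chd1 against wild type. The Chd1 log2 fold changes then ranged from -2.42 to -2.31, -1.71 to -1.64 and -0.74 to -0.62. The number of genes changed the same way in both Chd1-deficient comparisons but not called between elav>Chd1 and wild type, 1499, ranged from 788 (without Chd1-deficient replicate 1) to 1699 (without wild type replicate 2). It was 2953 with no filter (15891 genes tested), 570 at 10 TPM in 3 libraries (7472 tested) and 938 with only the 2 groups compared in each fit; the cause was not tested beyond the number of genes tested. At 10 TPM, 4994 genes differed between Chd1-deficient and elav>Chd1 and 4356 were called in both comparisons, with fewer genes tested. An absolute log2 fold change of at least 1, stricter by construction, left 3231, 1921 and 937 genes. The estimated correlation left 4, 5 and 5 lists. A higher correlation is not the only reason, because lists with an estimate below the preset 0.01 weakened too. For cuticle proteins in Chd1-deficient against wild type the estimate was -0.011, and the camera adjusted p went from 1.3e-07 to 0.017. Of single named genes, 4997 values kept their status, called or not, and 30 lost a call. Of single lists, 1667 results kept their status in the same sense, many of them never called. A call was lost by 71 (42 with the estimated correlation, 5 at 10 TPM, 3 with median-ratio scaling). A call was gained by 38 (10 at 10 TPM, 5 with no filter). Median-ratio scaling turned the balance of directions in Chd1-deficient against elav>Chd1, from 3847 higher and 3736 lower to 3764 and 4501. Replicate number as a block gave 9821, 7421 and 8527 genes. Libraries with the same number correlated at -0.16 to 0.11 after removal of group means, against a mean of -0.01 for other pairs. No pairing by number was seen, though a shared batch that touches few genes would not show. The count-based alternative test was not run, because it needs counts. The robust prior, chosen after seeing the data, gave 9840, 7579 and 8637 genes and ended the call of 1 named gene. The list test does not use this prior, so the 20, 14 and 22 lists could not change. TPM carry no sequencing depth, so values listed at 0 have no stated floor.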

Other observations

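Hemocyte markers were called in elav>Chd1 against wild type (7 of 9 higher, 2 lower, median 1.24, limma camera adjusted p = 0.003, adjusted p = 0.137 with an estimated correlation) and not in Chd1-deficient against wild type (6 higher, 3 lower, median 1.19, adjusted p = 0.201). Of their collagen genes, vkg stood at 6.61 ± 0.146 TPM in wild type, 16.92 ± 0.319 TPM in Chd1-deficient and 16.82 ± 0.341 TPM in elav>Chd1 libraries (n = 3, SD), and Col4a1 at 10.9 ± 0.071, 25.49 ± 1.43 and 26.48 ± 0.208 TPM. The clock gene list was not called in Chd1-deficient against wild type (8 of 13 higher, 3 lower, median 0.94, limma camera adjusted p = 0.115). It was called in elav>Chd1 against wild type with a smaller median (9 higher, 2 lower, median 0.52, adjusted p = 0.011, adjusted p = 0.345 with an estimated correlation). Between Chd1-deficient and elav>Chd1 the clock list was not called (camera adjusted p = 0.368). In Chd1-deficient against wild type its member tim stood at 18.39 ± 0.816 against 3.58 ± 0.235 TPM. The insulin-like peptide gene Ilp3 stood at 32.64 ± 0.993 TPM in Chd1-deficient, 7.52 ± 0.238 TPM in elav>Chd1 and 4.4 ± 0.270 TPM in wild type. The feeding-related peptide gene fit stood at 1175 ± 22.8, 125.9 ± 2.34 and 244.3 ± 3.91 TPM in the same order.

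Some abundant transcripts fell sharply in the Chd1-deficient libraries, and they were picked out after their values were seen. Among 157 genes with at least 1000 TPM in wild type, dhd, a germline thioredoxin, fell from 5288 ± 184.6 to 905.1 ± 39.3 TPM (log2 fold change -2.55) and stood at 4735 ± 135.2 TPM in elav>Chd1. The RNA regulator me31B fell by 0.92 on the log2 scale. Genes of the X chromosome had a median log2 fold change of -0.15 in Chd1-deficient against wild type, with 38.02% higher, and those of the other large arms medians of 0.02 (2L), 0.01 (2R), -0.09 (3L) and -0.04 (3R) with 45.47%, 45.38%, 41.59% and 43.09% higher.

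The explanations below were written down before their test except the ovary, Y chromosome and fat body tests, which were chosen only after the result was seen. The permutation p-values treat genes as independent, which members of a list are not. Eye, neuron and muscle genes were higher in the Chd1-deficient libraries. If only the share of ovary RNA had fallen, photoreceptor and digestive genes should have risen alike, but their medians differed by 1.38 (permutation p = 2.0e-05). The summed TPM of the ovary and eggshell list was not lower, at 31883 ± 1100 in Chd1-deficient against 27948 ± 3078 in wild type. Of its 25 genes, however, 16 were lower and 6 higher. A larger share of head tissue predicted that further eye genes rise by at least 1 and Malpighian tubule genes by less than 0.5. The medians were 1.81 and 0.70, a difference of 1.11 (permutation p = 0.0475). The Malpighian tubule genes exceeded their bound, so this prediction was not met. The test therefore neither shows nor excludes a change in tissue shares, which was not separated from an effect of Chd1 within cells.

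Male germline and accessory gland genes were higher in the Chd1-deficient libraries, which are labelled female. RNA from males predicted that male genes not looked at before also rise. Of the 32 tested, out of 45 in the files, 29 did (median 1.71), which male genes expressed in female tissue would give as well. Some, such as Sfp24Ba (1.92 against 0.162 TPM in wild type), passed the filter only through the Chd1-deficient libraries, which favoured a rise. Others, such as Dup99B (87.1 against 11.4 TPM), rose from above 1 TPM in wild type. Expression in female tissue predicted no more Y chromosome RNA than elsewhere. Each Chd1-deficient library summed to 7.33 TPM or more, against at most 0.62 in the other 6, which argues against this explanation as the whole cause. The sums stayed under the 10 TPM that the test had set for excluding it. Of 25 Y genes seen, 12 lay higher in every Chd1-deficient library than in the other 6. Examples, named after their values were seen, are CG45765 (1.92 to 4.825 against at most 0.338 TPM) and FDY (0.169 to 0.407 against at most 0.058 TPM). However, 10 of the 12 stayed under 1 TPM and the labels give no karyotype. Expression in female tissue was therefore not excluded for part of the pattern. RNA from males could give these values, but its share was not estimated. Ovary and eggshell transcripts were not lower in sum (31883 ± 1100 against 27948 ± 3078 TPM in wild type), although 16 of 25 were lower and 6 higher. Yp1, a yolk protein gene named after its values were seen, was higher (9517.3 to 9692.6 against 6666.1 to 7003.7 TPM). A sex difference from male RNA would enter both comparisons with the Chd1-deficient group, their overlap and the count of genes no longer called against wild type. It could also enter elav>Chd1 against wild type. There the male list had a median of -1.21 and Y chromosome RNA summed to 0.133 to 0.208 against 0.428 to 0.621 TPM. However, roX1 was not called in that comparison (1.95 against 1.98 TPM).

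Antimicrobial peptide genes were higher in the Chd1-deficient libraries. A larger share of fat body RNA predicted that fat body genes rise nearly as much, but the peptide median exceeded theirs by 1.37 (permutation p = 4.1e-04). An immune response predicted a rise of 6 receptors and regulators that Imd or Toll signalling induces, and all 6 rose, with a median of 1.38. Lists without an immune role rose more, such as muscle (median 2.25) and neuron markers (2.09). The rise of the 6 therefore does not single out an immune response. The whole list of immune receptors and signalling proteins was not called (19 of 37 higher, 16 lower, limma camera adjusted p = 0.478). Infection, loss of Chd1 and a difference in sex or tissue could each contribute to the higher peptide levels, and the labels do not separate them.

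The 10 ways to split 6 libraries into 3 and 3 cannot give a share under 0.05. The real split called the most genes in each comparison, 1 split of 10, with 9859, 7583 and 8642 genes against at most 1, 2 and 1 in any other. For lists, 4, 6 and 4 of the 10 splits called as many as the real one, which called 20, 14 and 22, and the highest other split called 21, 16 and 24. The other splits mix the genotypes 2 to 1 and so keep part of their difference.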
